A study of Mus musculus with 4 samples.

How the data were processed

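RNA sequencing of MC38, a mouse colon carcinoma cell line, was analysed in 4 libraries. The labels describe 2 libraries as wild type (WT) and 2 as Arid5a knockout (KO), with replicate numbers 1 and 2 in each group. The series design also names KPC cells, which were not analysed here. Per the labels' protocols, RNA was extracted with an RNeasy kit and libraries were made with a stranded TruSeq mRNA kit, which selects polyadenylated RNA. Per the submitters' processing notes, TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 0.1.19, Cufflinks 2.2.1 and the mouse build mm10 were used. Their settings, the gene annotation and the handling of strand were not given in the sources used here.

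The authors deposited FPKM values, fragment numbers divided by transcript length in kilobases and by the mapped fragments of the library, for 24346 gene symbols per library. FPKM corrects for transcript length and for library depth, but a few abundant transcripts can shift all other values of a library. FPKM sums were 600840 and 609180 in the libraries labelled WT and 638120 and 629440 in those labelled KO. The 10 highest symbols held 6.51% to 7.95% of these sums, and microRNA and small nucleolar RNA symbols held 4.34% to 6.21%. Such short genes receive unstable values from Cufflinks and were not eligible as named genes with the largest changes.

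Depth was estimated from the low values, which are multiples of what 1 fragment is worth. Among genes at or below 0.1 FPKM, 90.8% to 92.7% of the ratios between libraries lay within 1% of a ratio of whole numbers up to 6, against 4.38% to 11.3% by chance. The depth relative to WT replicate 1 was 0.767 in WT replicate 2, 0.670 in KO replicate 1 and 0.743 in KO replicate 2. With transcript lengths from GENCODE release M21, this gave about 15300000, 11800000, 10300000 and 11400000 fragments. In that fit 71 of 93 genes lay within 3% of the line. These depths are estimates, and fragment numbers derived from them depend on the transcript. Whole read counts per gene could not be recovered, because Cufflinks sums values over isoforms of different lengths, so no count model was used.

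Coordinates came from GENCODE M21 on GRCm38, the assembly that mm10 denotes. Of all symbols, 23268 (95.6%) matched 1 gene, as did 10409 (96.1%) of the 10827 symbols tested. No symbol of a mitochondrially encoded gene was listed. A total of 8155 symbols were listed at 0 in all 4 libraries.

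The libraries labelled KO were compared with those labelled WT with limma 3.58.1 in R 4.3.3. Values were transformed to log2(FPKM + 1), genes with a mean of at least 1 FPKM over the 4 libraries were kept, and lmFit and eBayes with a mean-variance trend were applied without a block. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of genes near or below 1 FPKM. Errors of log2 changes are standard errors (SE), and errors of FPKM means are standard deviations (SD) over 2 libraries. Data simulated for this comparison held 10678 genes, with changes placed only in genes above about 5 FPKM in the libraries labelled WT. Of 67 simulated changes of 0.5 (log2), 86.6% were recovered. All of the simulated changes of 1 and 2 were recovered, and 7 of 198 calls (3.54%) were false. The simulated noise was drawn from the spread that limma had fitted, independently for each gene and library. A low share of false calls was therefore largely given in advance and is no check on the data. Recovery at lower levels was not measured. Far fewer genes were changed than the 47.6% called in the data, so the share of false calls there may differ.

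The test, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The 26 gene lists and 4 lists defined by symbol pattern were tested with camera in limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the gene lists and over the pattern lists. Each was repeated with camera at an estimated correlation and with fry. Named genes were Arid5a, Ido1 and Ccl2, the 12 largest rises and the 12 largest falls, and up to 4 called members of each list with the largest absolute change. The genes of the second part had to be called, with separated groups and a higher group mean of at least 5 FPKM. Their symbols could not be those of predicted genes, clones, microRNAs or small nucleolar RNAs. Of the 12 largest falls, 1 is not reported here. Other genes named in the text were chosen after their values were seen. Most of them are the called members of a list of which 5 or fewer went in 1 direction.

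Alternatives covered the pseudocount, the filter, 3 further scalings between libraries, the moderation of variances, the replicate number as a block, and the omission of each library. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for reading the data and drawing. Nothing in the labels says whether the 2 libraries of a group came from separate cultures or clones. Between them, the chi-square per gene over 691 genes with 1 annotated transcript, from estimated fragments, was 1.47 for the WT pair and 1.60 for the KO pair, where counting noise alone gives about 1. Between groups it was 20.3 to 24.5. The p-values therefore measure a spread that is little above counting noise and that may be technical.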

Results

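Gene expression was measured by RNA sequencing in MC38 cells, a mouse colon carcinoma line, in 2 libraries labelled wild type (WT) and 2 labelled Arid5a knockout (KO). Between 14314 and 14605 of 24346 gene symbols were above 0 FPKM in each library, and 10748 to 10779 reached 1 FPKM. Estimated depth was 15300000 and 11800000 fragments in the libraries labelled WT and 10300000 and 11400000 in those labelled KO. Across genes, the Pearson correlation of log2 values was 0.978 between the WT replicates and 0.982 between the KO replicates. It was 0.954 to 0.960 between libraries of different groups. Genes are not independent replicates.

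Arid5a, the targeted gene, encodes an AT-rich interaction domain protein that binds and stabilises mRNAs. It was higher, not lower, in both libraries labelled KO. Its level was 2.16 and 1.77 FPKM there, against 0.225 and 0.124 FPKM in the libraries labelled WT. The log2 change was 1.33 ± 0.13 (SE; limma, adjusted p = 0.0013), on a scale that understates it, since the ratio of the mean FPKM values was 11.3. Arid5a lies on chromosome 1 from 36307733 to 36324029 on the plus strand (GRCm38). Depending on the transcript, these levels correspond to about 1 to 18 and 0 to 8 fragments in the libraries labelled WT, and 5 to 118 and 5 to 107 in those labelled KO. The values per gene do not show which exons the fragments came from, and the deleted part of the gene is not given in the labels. Because the targeted gene goes against the group labels, every direction below refers to the labels as deposited, not to a loss of Arid5a.

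**Figure D1:**
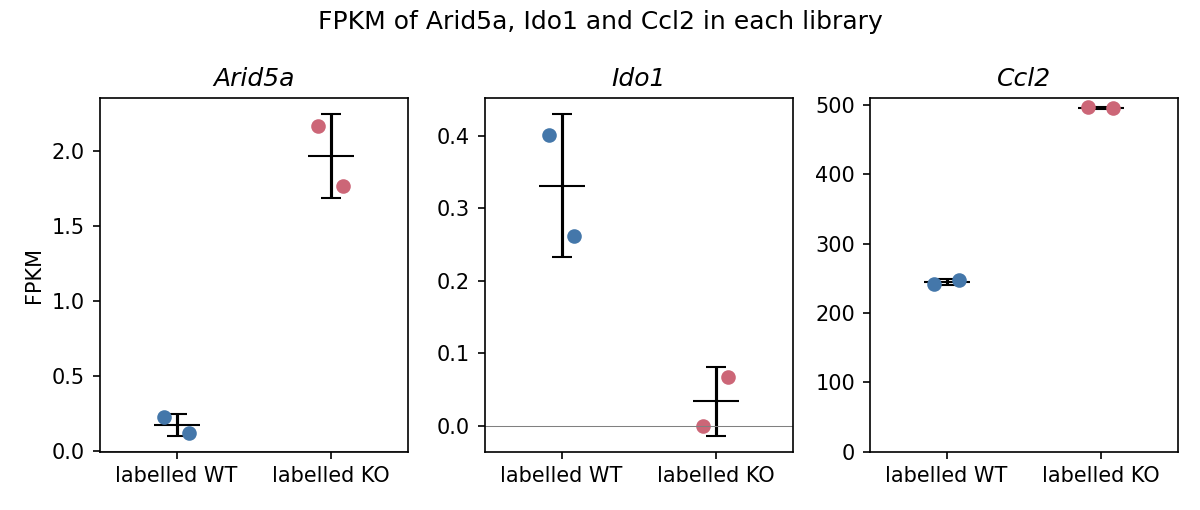
FPKM (y axis) of Arid5a, Ido1 and Ccl2 in the libraries labelled WT and KO (x axis). Points are single libraries, wide bars are group means and whiskers are the SD over 2 libraries. Arid5a and Ccl2 were higher and Ido1 was lower in both libraries labelled KO, with Ido1 below 0.5 FPKM in every library.

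Ccl2 and Ido1, mRNAs reported as Arid5a targets, went in opposite directions. Ccl2, a chemokine that attracts monocytes (chromosome 11, 82035571 to 82037453, plus strand), was 244 ± 4.15 FPKM (SD) in the libraries labelled WT and 495 ± 1.27 FPKM in those labelled KO. Its log2 change was 1.02 ± 0.026 (SE; limma, adjusted p = 4.24e-05). Ido1, which converts tryptophan toward kynurenine (chromosome 8, 24584136 to 24597009, minus strand), was at 0.401 and 0.261 FPKM in the libraries labelled WT. It was at 0 and 0.0674 FPKM in those labelled KO. These values correspond to about 8 to 9, 4, 0 and 1 fragments, and Ido1 was below the filter for the test. With no filter its log2 change was -0.36 ± 0.071 (SE; limma, adjusted p = 0.0245). Among the 6 reported target mRNAs, the only other one above the filter was Stat3, a transcription factor activated by cytokines, at -0.50 ± 0.048 (SE; adjusted p = 0.00132). Of the 2 tested, 1 was higher and 1 lower, also when adjusted over the list alone, and the list was not called by camera (adjusted p = 0.793). Ido1 and Ccl2 are known from this study and may have been picked on these samples, so this list is not independent evidence.

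The comparison asks which transcripts differ between WT and Arid5a knockout MC38 cells. In the libraries labelled KO, genes of glycolysis and the hypoxia response, amino acid stress, cholesterol synthesis and antioxidant defence were higher. Interferon-stimulated genes and the MHC class I genes that present antigen to T cells were lower. These are calls of gene lists by camera at a preset correlation, and each was lost with an estimated correlation (adjusted p of 0.158 to 0.167). The chemokines Cxcl1, Cxcl3 and Cxcl5 were among the largest rises. Of 10827 genes tested, 5159 (47.6%) were called with limma at a Benjamini-Hochberg adjusted p under 0.05. Of these, 2641 were higher and 2518 lower in the libraries labelled KO. The median absolute log2 change of called genes was 0.34, and 109 higher and 184 lower genes reached an absolute log2 change of 1. Both libraries of 1 group lay above both of the other for 8394 tested genes (77.5%), where chance gives 33.3%. Called genes made up 36.5% of the lowest tertile of expression, 47.1% of the middle tertile and 59.3% of the highest. The number called was 3325 without WT replicate 1 and 3216 without WT replicate 2.

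The largest rise was that of Tex101, a germ cell glycoprotein, from 0 and 0.1 FPKM to 39.6 and 42 FPKM, a log2 change of 5.32 ± 0.080 (SE; limma, adjusted p = 3.1e-05). Tollip, an adaptor of innate immune signalling, followed at 3.37 ± 0.092. It was listed at 0 in both libraries labelled WT and at 8.95 and 9.79 FPKM in those labelled KO. Its log2 change, like that of Tex101, therefore depends on the pseudocount. The neutrophil chemokine Cxcl3 was at 3.08 ± 0.13, with Cxcl1 at 2.44 ± 0.090 and Cxcl5 at 2.21 ± 0.11. Further rises were those of Glmp, a lysosomal membrane protein (2.75), Rec114, a meiotic recombination factor (2.60), and Adm2, a peptide of the adrenomedullin family (1.93). Chac1, which degrades glutathione, rose by 2.23, Lcn2, an iron-siderophore binding protein, by 2.15, and the pseudokinase Trib3 by 2.01. These last 3 genes lie on chromosome 2, whose genes shifted upward as a whole (below). Akr1b3, aldose reductase, was listed at 0 and 2.34 FPKM against 7.96 and 12 FPKM, a large spread within the libraries labelled WT. Its call was lost at a pseudocount of 0.1 (limma, adjusted p = 0.0536) and with robust moderation of variances (limma, adjusted p = 0.142). Without KO replicate 2 its log2 change was 2.29. Among all 24 genes with the largest changes, the highest adjusted p (limma) was 0.0168.

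The largest fall, -6.63 ± 0.16 (SE), was that of Atp6v0c-ps2, a processed pseudogene of a proton pump subunit. It fell from 124 and 88.9 FPKM to 0.107 and 0.0369 FPKM. Its parent gene Atp6v0c, chosen for its sequence after the values were seen, was 133 and 154 FPKM against 267 and 263 FPKM. The sum of both was 257 and 243 FPKM in the libraries labelled WT and 267 and 263 FPKM in those labelled KO. Near-identical copies share reads, so neither change can be read as that of 1 gene. Ndufs5, a complex I subunit, was 8.53 and 36 FPKM against 0.0316 and 0.00675 FPKM, a large spread within the libraries labelled WT. Its value in KO replicate 2 is below what 1 whole fragment would give over the length of the gene. Shared reads are therefore not excluded for Ndufs5 either, and the size of its fall is uncertain. Ifi27l2a, an interferon-induced gene, changed by -3.49, the chemokine Ccl8 by -2.98 and Oas2, an antiviral oligoadenylate synthetase, by -2.82. Enpp2, the secreted enzyme autotaxin, changed by -2.79, the urea transporter Slc14a1 by -2.34 and Ace, angiotensin-converting enzyme, by -2.33. Ly6a, a surface marker of stem and activated cells, changed by -2.29, Mndal of the interferon-inducible p200 family by -2.21, and Sdpr, a component of caveolae, by -2.12.

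Interferon response genes were lower in the libraries labelled KO. Of 37 tested, 30 fell and 4 rose, also when adjusted over the list alone, with a median log2 change of -0.47 (camera, adjusted p = 7.71e-09; adjusted p = 0.158 with an estimated correlation). Oas2 fell most, followed by the RNA sensor regulator Dhx58 (-1.74 ± 0.12), the nucleic acid sensor Zbp1 (-1.66 ± 0.071) and Ifit3 (-1.55 ± 0.095). The 4 that rose were Irf7 (1.01), Oasl1 (0.39), Rsad2 (0.38) and Irf1 (0.26). Genes of MHC class I antigen presentation were lower too, with 14 of 18 tested falling and 2 rising, also when adjusted over the list alone. Their median was -0.61 (camera, adjusted p = 1.48e-06; adjusted p = 0.167 with an estimated correlation). H2-K1, a classical class I heavy chain, fell from 1017 and 1012 FPKM to 388 and 396 FPKM, a log2 change of -1.37 ± 0.024. H2-D1 changed by -1.30 ± 0.025, H2-Q4 by -1.65 ± 0.062 and the immunoproteasome subunit Psmb9 by -1.43 ± 0.051. The shared light chain B2m went from 1552 and 1573 FPKM to 671 and 662 FPKM. Class I genes are close paralogs that can share reads, so the values of single heavy chains are uncertain. The 2 that rose, Calr and Pdia3, are general chaperones of the endoplasmic reticulum. Of 21 leukocyte markers in the tables, 19 were below the filter, and the other 2 were lower in the libraries labelled KO. Cd68 was 6.14 and 5.8 FPKM against 1.03 and 1.67 FPKM, and S100a8 was 1.77 and 4.61 FPKM against 1.06 and 0 FPKM. The call of S100a8 (adjusted p = 0.0489) was lost in 11 of its 16 alternatives (adjusted p from 0.0529 to 0.187), among them the omission of WT replicate 2 (0.187) or KO replicate 2 (0.164).

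Chemokines and cytokines were mostly higher, with 10 of 18 tested rising and 2 falling, also when adjusted over the list alone, and a median of 0.31 (camera, adjusted p = 0.00289; adjusted p = 0.249 with an estimated correlation). The rises were led by Cxcl3, Cxcl1 and Cxcl5. The 2 that fell were Vegfc, a lymphatic growth factor (-1.80 ± 0.043), and Tgfb1 (-0.25). The chemokine Ccl8, which is not a member of this list, fell further (-2.98). Immune checkpoint and suppressive factors were mostly lower, with 7 of 12 falling and 2 rising, also when adjusted over the list alone, and a median of -0.41 (camera, adjusted p = 0.0221; adjusted p = 0.401 with an estimated correlation). Ido2, a paralog of Ido1, changed by -1.70, the costimulatory receptor Tnfrsf9 by -1.19 and Ptges, a prostaglandin E synthase, by -0.80. Nos2, the inducible nitric oxide synthase, rose by 2.15 ± 0.11 from 0.103 and 0.135 FPKM to 4.32 and 3.66 FPKM, and Pvr rose by 0.48. The leukocyte markers Cd68 and S100a8 were lower in the same libraries.

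Hypoxia and glycolysis genes rose together, with 25 of 28 tested higher and 0 lower. Adjusted over the list alone, 25 were higher and 1, the carbonic anhydrase Car9 (-0.20), was lower. Their median was 0.53 (camera, adjusted p = 6.75e-11; adjusted p = 0.158 with an estimated correlation). The mTORC1 inhibitor Ddit4 rose by 1.82 ± 0.031, from 44.2 and 45 FPKM to 162 and 158 FPKM. The mitophagy receptor Bnip3 rose by 1.35 ± 0.042, Ndrg1 by 1.20 ± 0.036 and the oxygen sensor Egln1 by 0.86 ± 0.037. Of 25 tested genes of the ATF4 and unfolded protein responses, 20 rose and 2 fell, also when adjusted over the list alone, with a median of 0.50 (camera, adjusted p = 4.36e-08; adjusted p = 0.158 with an estimated correlation). Atf4 itself, a transcription factor of amino acid stress, rose by 1.03 ± 0.026 and the cystine transporter Slc7a11 by 1.60 ± 0.073, beside Chac1 and Trib3. The 2 that fell were Xbp1 (-0.31), which directs the unfolded protein response, and the chaperone Dnajc3 (-0.14). Dnajc3 lost its call whichever library was left out, with adjusted p from 0.0546 to 0.148. Cholesterol synthesis genes rose in 20 of 23 cases with 0 falling, also when adjusted over the list alone, with a median of 0.35 (camera, adjusted p = 1.5e-07; adjusted p = 0.158 with an estimated correlation). Dhcr7 rose by 0.87, Hmgcs1 by 0.76, Fdps by 0.57 and Idi1 by 0.53. NRF2 targets rose in 13 of 18 cases and fell in 1, or 14 and 2 when adjusted over the list alone, with a median of 0.36 (camera, adjusted p = 3.27e-05; adjusted p = 0.167 with an estimated correlation). Besides Slc7a11, the transketolase Tkt rose by 0.97, heme oxygenase Hmox1 by 0.83 and malic enzyme Me1 by 0.64. The 1 that fell, Gstm1 (-0.44), lost its call without WT replicate 2 (adjusted p = 0.0556) and without KO replicate 1 (adjusted p = 0.0749).

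**Figure D2:**
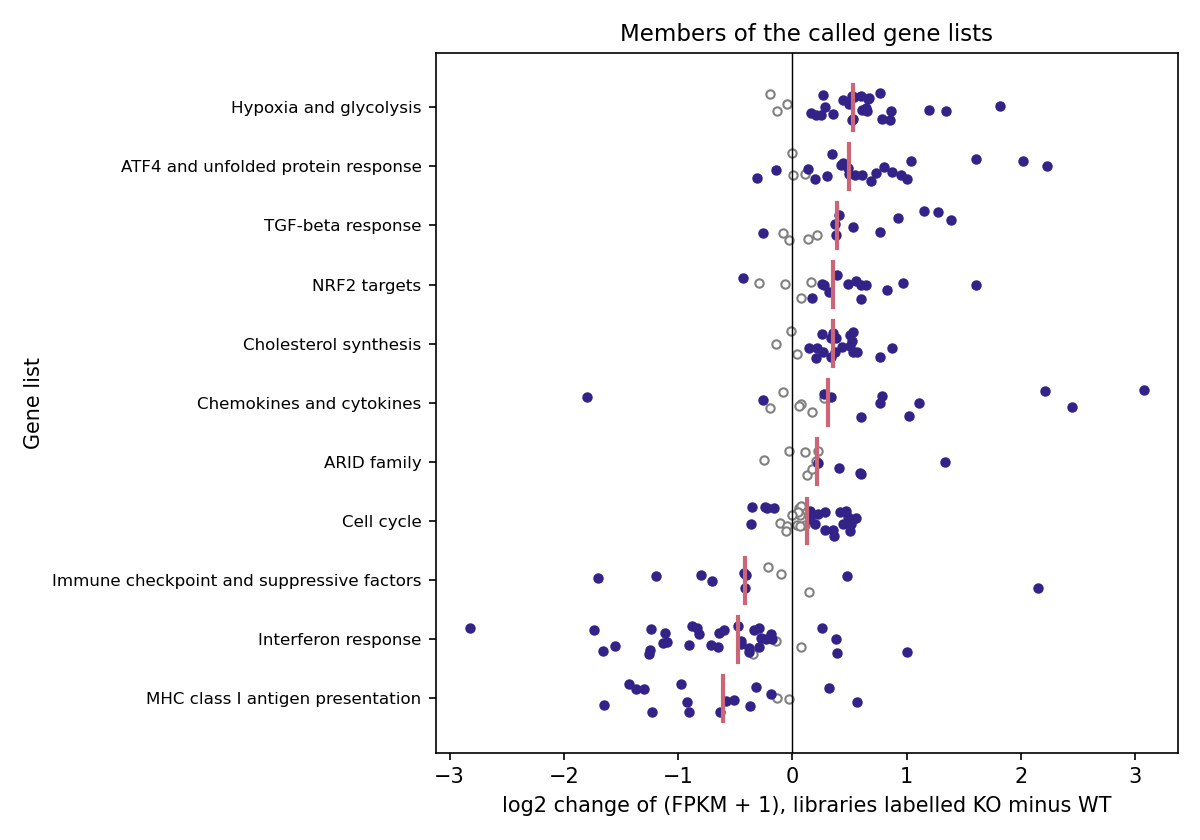
Log2 change of (FPKM + 1), libraries labelled KO minus WT (x axis), for the tested members of the 11 called gene lists (y axis). Filled points are called genes, open points are genes not called, and vertical bars are list medians. The medians ran from -0.61 for MHC class I antigen presentation to 0.53 for hypoxia and glycolysis.

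Of 14 tested genes of the TGF-beta response, 9 rose and 1 fell, also when adjusted over the list alone, with a median of 0.39 (camera, adjusted p = 0.000833; adjusted p = 0.296 with an estimated correlation). The matricellular protein Cyr61 rose by 1.39 ± 0.032, Id1, an inhibitor of differentiation on chromosome 2, by 1.28 ± 0.042, the inhibitory Smad6 by 1.15 and Skil by 0.93. The ligand Tgfb1 fell by 0.25. Cell cycle genes rose in 16 of 32 cases and fell in 5, or 18 and 5 when adjusted over the list alone, with a median of 0.13 (camera, adjusted p = 0.00486; adjusted p = 0.377 with an estimated correlation). Mcm3 of the replicative helicase rose by 0.56, the mitotic kinases Bub1 and Aurkb by 0.51 and 0.51, and the replication clamp Pcna by 0.50. The 5 that fell were Foxm1, Birc5, Cenpe, Cdc20 and Cdc6, with log2 changes from -0.16 to -0.36, and Cdc6 lost its call whichever library was left out (adjusted p from 0.0837 to 0.145). Of 12 tested ARID family genes, 5 rose and 0 fell, or 6 and 0 when adjusted over the list alone, with a median of 0.21 (camera, adjusted p = 0.0214; adjusted p = 0.304 with an estimated correlation). This list includes Arid5a itself. Jarid2, a Polycomb cofactor, rose by 0.60, Arid3a by 0.59, the histone demethylase Kdm5b by 0.41 and Kdm5c by 0.22. Kdm5b was not called without WT replicate 1 (adjusted p = 0.0537), nor was Kdm5c without WT replicate 1 (0.062) or WT replicate 2 (0.0536). The call of the list was lost at a filter of 5 FPKM (adjusted p = 0.342).

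Extracellular matrix genes changed in both directions, with 9 of 20 tested rising and 5 falling, also when adjusted over the list alone (camera, adjusted p = 0.576). Collagen genes parted, with Col12a1 rising by 1.78 ± 0.10 and Col1a1 by 1.27 ± 0.11, and Col3a1 changing by -1.88 ± 0.063. The proteoglycan Dcn fell by 1.70 ± 0.13. Of 10 mesenchymal markers tested, 3 rose and 4 fell, or 4 and 4 when adjusted over the list alone (camera, adjusted p = 0.576), with S100a4 at -1.01 and fibronectin Fn1 at -0.91. The median of this list was 0.003 and its mean -0.14. Of 11 transcription factors of the epithelial-mesenchymal transition, 3 rose and 1 fell, or 3 and 0 when adjusted over the list alone (camera, adjusted p = 0.771). Foxc2 rose by 0.69 and Zeb1 by 0.53. Of 26 epithelial markers, including Cdh1 and Epcam, 24 were below the filter. Jup, plakoglobin, fell by 1.25 ± 0.060, and the tight junction protein Tjp1 rose by 0.15. Tjp1 was not called without WT replicate 1, WT replicate 2 or KO replicate 2 (adjusted p of 0.121, 0.119 and 0.116). The list of 2 tested genes was not called (camera, adjusted p = 0.689), and both were called when adjusted over the list alone.

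Other signalling lists were not called. NF-kB targets rose in 6 and fell in 4 of 20 cases, or 7 and 5 when adjusted over the list alone (camera, adjusted p = 0.59), with the inhibitor Nfkbia rising by 0.84 and the adhesion molecule Vcam1 at -0.85. STAT3 targets rose in 6 and fell in 6 of 16 cases, or 6 and 7 when adjusted over the list alone (camera, adjusted p = 0.957). Cebpb rose by 1.53 and Timp1 fell by 0.70, and the list's median was -0.02 while its mean was 0.11. Immediate early genes rose in 7 and fell in 8 of 21 cases, or 8 and 8 when adjusted over the list alone (camera, adjusted p = 0.865). Egr1 fell by 1.73 and Jund rose by 1.14, and the list's median was 0.045 while its mean was -0.023. Targets of p53 rose in 5 and fell in 5 of 18 cases, or 6 and 6 when adjusted over the list alone (camera, adjusted p = 0.957), with a median of -0.04 and a mean of 0.10. Gdf15 rose by 1.23 and the cell cycle inhibitor Cdkn1a by 1.04, and the death receptor Tnfrsf10b fell by 0.66. Wnt targets rose in 2 and fell in 4 of 9 cases, also when adjusted over the list alone (camera, adjusted p = 0.361), with the Wnt antagonist Apcdd1 at -1.97 and the transcription factor Tcf7 at -0.72. Genes of the tryptophan, kynurenine and aryl hydrocarbon receptor pathway rose in 5 and fell in 6 of 12 cases, also when adjusted over the list alone (camera, adjusted p = 0.694). Tiparp fell by 1.10 and Cyp1a1 rose by 0.83.

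Markers of other cells and signs of RNA quality were compared in the same way. The 2 leukocyte markers above the filter gave no called list (camera, adjusted p = 0.156), and both were called when adjusted over the list alone. Of 5 fibroblast markers, 1 rose (Col1a1) and 2 fell (Col3a1 and Dcn), also when adjusted over the list alone (camera, adjusted p = 0.655). The endothelial list held 1 tested gene, Egfl7, at -0.18 ± 0.053 (SE; camera, adjusted p = 0.576). Egfl7 was called over all genes and over the list alone, but lost its call whichever library was left out (adjusted p from 0.0534 to 0.176). The 5 sex-chromosome transcripts used to tell clones apart were below the filter. Symbols starting with Rps or Rpl and a digit, without pseudogenes, were taken as ribosomal protein genes. Other genes that share this pattern were not removed. Of this list, 67 of 89 rose and 4 fell, or 69 and 4 when adjusted over the list alone. Its median was 0.18 (camera, adjusted p = 1.05e-11, and 0.155 with an estimated correlation). Under quantile normalization the median was 0.04 and the call was lost (adjusted p = 0.21). Histone genes (9 tested, 1 higher and 2 lower; camera, adjusted p = 0.994) and predicted genes (139 tested, 27 higher and 42 lower; camera, adjusted p = 0.255) were not called as groups, and their counts were the same when adjusted over the list alone.

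Changes were not spread evenly over the genome. Of 832 tested genes on chromosome 2, 456 were higher and 78 lower in the libraries labelled KO. Their median log2 change was 0.23, against -0.012 for genes on other chromosomes, and 77.4% of them lay above 0. Of the genes named above, Chac1, Lcn2, Trib3, Id1, Bub1, Pcna, Cebpb and Pdia3 rose and lie on this chromosome, as do Zbp1, Ptges, Egfl7 and B2m, which fell. Chromosome 12 had a median of 0.15, with 152 of 364 genes higher and 32 lower. Chromosomes 13, 15 and 11 had medians of -0.12, -0.11 and -0.098.

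**Figure D3:**
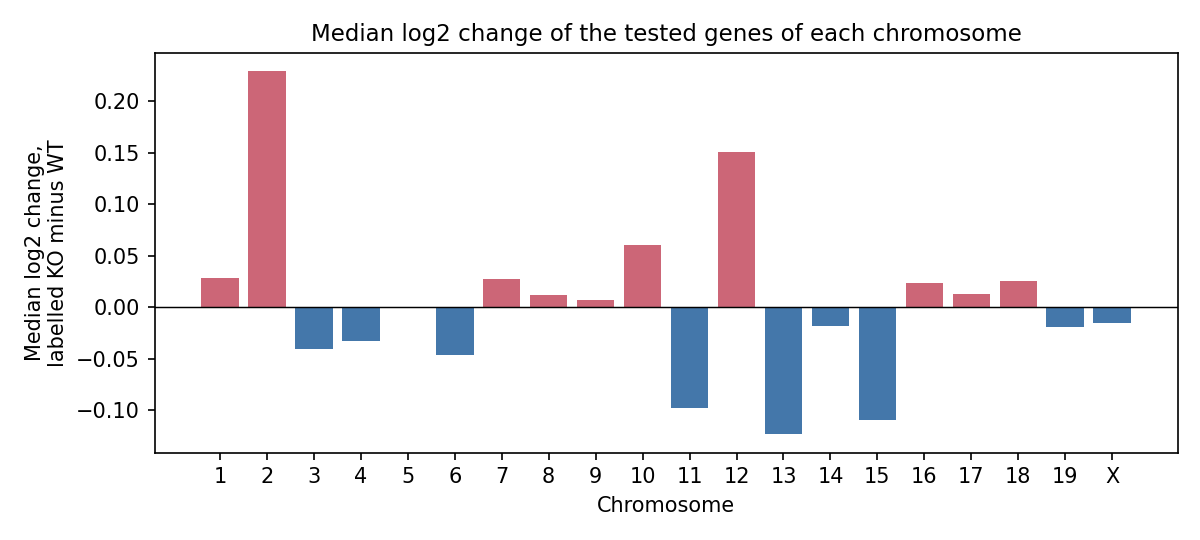
Median log2 change of (FPKM + 1), libraries labelled KO minus WT (y axis), over the tested genes of each chromosome (x axis). Bars above 0 are red and bars below 0 are blue, and the tallest is that of chromosome 2 at 0.23.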

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

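The alternatives were fixed before the data were examined, except the omission of small RNA, predicted gene, clone and pseudogene symbols and the setting of each chromosome's median to 0, which were added after seeing the data. Arid5a stayed higher in the libraries labelled KO and called in all alternatives that test it (a filter of 5 FPKM removes it), with adjusted p (limma) up to 0.0102 (without WT replicate 2). Its log2 change was 2.93 at a pseudocount of 0.1 and 0.43 at 5. The 5159 calls became 3216 to 3974 when 1 library was left out, where the lone library of a group is assumed to vary like the other group. The other alternatives kept 84% to 99.7% of the calls, and the median log2 change of all genes, 0.0056, lay between -0.0027 and 0.011 under the 3 scalings. The 109 genes higher by a log2 change of 1 or more became 175 at a pseudocount of 0.1, 40 at a pseudocount of 5 and 61 at a filter of 5 FPKM. The 184 lower genes became 65 and 100 at the latter settings. A larger pseudocount shrinks changes by construction. Of the 25 gene lists with a tested gene, 11 were called by camera, 0 with an estimated correlation and 23 with fry, which does not compare a list with other genes. The estimated correlation gave adjusted p of 0.158 (hypoxia and glycolysis, interferon, ATF4, cholesterol), 0.167 (MHC class I, NRF2), 0.249 (chemokines), 0.296 (TGF-beta), 0.304 (ARID family), 0.377 (cell cycle) and 0.401 (checkpoint). It rests on 2 residual degrees of freedom. The ARID family lost its call at a filter of 5 FPKM (0.342). The 1 called pattern list, ribosomal proteins, became 0 under quantile normalization (adjusted p of 0.21) and with an estimated correlation (0.155). Why quantile normalization ended it was not tested. Of 100 other named genes tested, 89 kept their call and direction in all alternatives, and 0 reversed. The others were Akr1b3, Ndufs5, Kdm5b, Tjp1, Serpinf1, Cdh2, Snai2, Prrx1, Lef1, S100a8 and Egfl7, which lost their call in 45 of their 184 alternatives.

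The replicate numbers are not said to mark a shared culture or day, so no pairing was assumed. With a replicate block 4673 genes were called, and deviations of equal numbers correlated at 0.138 across genes. The other 2 splits of the 4 libraries called 1 and 0 genes with limma (23 and 14 at an unadjusted p under 0.05). Each side of these splits holds 1 library of each label, so the difference between the groups adds to the residual spread. Few calls were therefore fixed in advance, and these numbers are no check on false calls. In any case, 3 splits are too few for a share under 0.05. Alternatives for counts, and a count test on recovered reads, were not run, since the values are FPKM summed over isoforms. The median SE was 0.092 in the lowest tertile of expression (1.01 to 8.22 FPKM) and 0.038 in the highest. The effect of depth itself was not tested.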

Other observations

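The gene families in this paragraph and the next were chosen after seeing the data and were tested with camera (Benjamini-Hochberg over 12 families). The adjustment does not correct for that choice, so a call of a family describes these data and is not independent evidence. Enzymes of serine and one-carbon metabolism were higher in the libraries labelled KO, with 8 of 12 called upward and 1 downward and a median log2 change of 0.49 (camera, adjusted p = 0.000184; adjusted p = 0.289 with an estimated correlation). Of these 8, 5 are also members of the ATF4 list, so the family is not a separate observation. Phgdh, the first enzyme of serine synthesis, went from 211 and 220 FPKM to 359 and 357 FPKM. Aldh1l2, a mitochondrial folate enzyme, rose by 1.26 and Psph by 0.80. Amino acid transporters rose in 8 and fell in 3 of 14 cases (camera, adjusted p = 0.0125; adjusted p = 0.479 with an estimated correlation), led by Slc7a11 and the glycine transporter Slc6a9 (1.25 ± 0.056). Of the 14, 2 are also in the ATF4 list (Slc7a11 and Slc7a5) and 3 in the tryptophan list, so this family is not fully separate either. Cytosolic aminoacyl-tRNA synthetases rose in 12 and fell in 6 of 20 cases and were not called (camera, adjusted p = 0.0533), with Cars rising from 15.9 and 15.6 FPKM to 48.6 and 50 FPKM. Their mitochondrial counterparts (17 tested, 1 higher and 3 lower) and the TCA cycle (18 tested, 4 higher and 6 lower) were not called (camera, adjusted p = 0.502 for both). The 20S proteasome core (14 tested, 5 higher and 3 lower) and the CCT chaperonin (8 tested, 3 higher and 0 lower) were not called either (camera, adjusted p = 0.332 for both).

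Interferon-inducible GTPases, which act against intracellular pathogens, fell in 9 of 10 cases, with a median of -0.90 (camera, adjusted p = 2.53e-05; adjusted p = 0.289 with an estimated correlation). Gbp3 changed by -1.25 and Igtp by -1.13. This family shares members with the interferon list, and so is not a separate observation. All 6 tested members of the interferon-inducible p200 family fell, with a median of -0.94 (camera, adjusted p = 0.0012; adjusted p = 0.381 with an estimated correlation). Schlafens fell in 3 of 5 cases and were not called (camera, adjusted p = 0.0958). Semaphorins and plexins, guidance cues and their receptors, fell in 9 of 12 cases and rose in 0, with a median of -0.33 (camera, adjusted p = 0.00255; adjusted p = 0.381 with an estimated correlation). Sema3a went from 34.8 and 33.9 FPKM to 10.3 and 10.2 FPKM. Complement and coagulation genes rose in 3 and fell in 5 of 10 cases and were not called (camera, adjusted p = 0.244). Of these, C1s1 (-1.69), C2 (-1.61) and C1ra (-1.19) fell and C3 was 0.475 and 0.43 FPKM against 1.71 and 1.7 FPKM. The medians of the called families kept their sign under the 3 other scalings.

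In the tests of the 3 patterns that follow, those of expression level and of GC content on chromosome 2 and that of scaling for the interferon genes were set before their results were seen, and the others after. Arid5a was higher in both libraries labelled KO. Extra copies of the region are argued against by the 26 tested genes within 2 Mb, whose median log2 change was 0.083 and upper quartile 0.29, against 1.33 for Arid5a. Labels exchanged between the 2 groups cannot be told apart from a knockout that leaves or raises Arid5a mRNA. Ccl2 (1.02) and Ido1 went in opposite directions, and Ido1 rests on a few fragments. Stat3, the other reported target above the filter, changed by -0.50, opposite to Ccl2, so the reported targets remain divided. The values per gene cannot decide between these explanations, since the altered part of the gene is not given in the labels. Counting noise at the low level of Arid5a stays open too. The highest adjusted p (limma) was 0.00646 over the 12 alternatives that kept all 4 libraries, but these refit the same 4 values. If only the shortest transcript was expressed, the values rest on about 1, 0, 5 and 5 fragments. If only the longest was, the numbers are 18, 8, 118 and 107. WT replicate 2 was listed at 0.124 FPKM, which 0 fragments cannot give, so the shortest transcript alone does not account for all 4 values. Which transcript was expressed is not known.

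Genes on chromosome 2 were higher in the libraries labelled KO as a group (median 0.23). Expression level is argued against by 10000 lists from other chromosomes matched on mean expression, whose highest median was 0.033. GC content and transcript length are argued against by a fit on both, after which the difference from other chromosomes was 0.236, against 0.241 before. The bootstrap interval at 95% was 0.214 to 0.264. It resampled genes as if they were independent, so it does not measure the spread between libraries or cultures. A candidate explanation is a copy number difference along the whole chromosome between the cell populations. All 10 bins of 20 Mb had a median above that of the other chromosomes, the lowest at 0.128 and the highest at 0.315. The bins hold the same genes as the pattern, and this test was set after the pattern was seen, so its result was nearly given. A broad effect on expression would give the same. No DNA was measured, so a copy number difference remains a hypothesis, and an effect of Arid5a on many genes of the chromosome was not tested.

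Interferon response and MHC class I genes were lower in the libraries labelled KO. Leukocytes in the libraries labelled WT are argued against by 6 markers chosen after the data were seen, Ptprc, Coro1a, Laptm5, Tyrobp, Fcer1g and Lyz2. Their highest value there was 1.2 FPKM, while H2-K1 fell from 1017 and 1012 FPKM to 388 and 396 FPKM. The markers did not share a direction. Coro1a, Laptm5 and Fcer1g were higher in the libraries labelled KO, Ptprc and Lyz2 were lower, and Tyrobp was 0 in every library. Cd68 and S100a8, the only markers of the leukocyte list above the filter, are not among these 6 and were higher in the libraries labelled WT. Cd68 was 6.14 and 5.8 FPKM there and S100a8 1.77 and 4.61 FPKM, so a small number of such cells was not excluded. Scaling between the libraries is argued against by the median of the interferon list, which was at most -0.456 under the 3 other scalings. Whether the lower values come from Arid5a or from a difference between clones or cultures was not tested, because each group may hold 1 clone and the level of Arid5a goes against the labels.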
